A study of Mus musculus with 45 samples.

How the data were processed

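RNA of mouse hepatocyte organoids and freshly isolated hepatocytes was selected by poly(A), per the labels, and 45 libraries in 15 groups of 3 were analysed. Groups and replicate numbers were taken from the sample titles, which name the medium, the hormone and the day. Per the submitters' processing notes, reads were aligned with STAR to mm10, counted per gene with featureCounts of Subread and turned into values with edgeR, with no versions given; the strand setting and the annotation are not given in the sources used here. The deposited values are a signal made by the authors, gene counts scaled to an effective library size, which is the library total times a factor. Columns sum to 838257 to 1310926, so they are not plain CPM, though called CPM in the text. The factors implied run from 0.763 to 1.19. Whole reads were recovered from the steps between low values, and 100% of values were whole in the library with the lowest share, within a tolerance of 0.25 reads (largest deviation 0.232). Recovered totals were 16159953 to 47010541 reads per library. PCR reads without molecular identifiers are not independent molecules. The design had been fixed for CPM, and the test used is the one that design names, on the deposited values. On the recovered reads, edgeR's quasi-likelihood test called 5829 to 11102 genes per comparison. No pair of replicates was identical (45 pairs, 0 identical; chi-square per degree of freedom 1.30 to 19.1).

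Genes with a value of at least 1 in at least 3 libraries were kept (13248 of 16625; 26 were at 0 in every library), and log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), with one mean per group over all 45 libraries and no replicate block. Each gene had 30 residual degrees of freedom, 42.15 with the prior, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The 22 contrasts were 19 pairwise ones and 3 interactions, for T3 with dexamethasone, T3 with day, and truncated beta-catenin with medium. Gene lists for liver functions, zonation, hormone and growth factor responses, stress and other cell types, 32 in number, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, where at least 5 members were measured (31 lists). Of the 187 list results described, 184 were called and 177 of these also held with an estimated correlation; where one did not, its p is printed beside it. The share of the 100 genes highest in hepatocytes and the Spearman correlation across tested genes with the hepatocyte mean were computed per library and compared with exact two-sided permutation tests. The fit was tested on simulated data for T3 against RGF on day 6, 13248 genes with 50 changed at each of 4 sizes: limma found 33 at 1.25-fold, 46 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, with 10 false calls. Named genes followed a rule fixed before the data were examined: per comparison, the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in the higher group and no overlap of libraries, up to 4 members with the largest change per described list, and a fixed set of hepatocyte, zonation, hormone, cell cycle and bile duct genes with members of the thyroid, glucocorticoid and Wnt lists. Genes named outside it are said to be chosen after their values were seen. A fold is given for a gene only where each group held at least 4 recovered reads. Gene locations are from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, matched by symbol (16408 genes with one location, 28 with several, 189 with none). Reads of near-identical genes, such as the Mup, Ces, Serpina1 and Cyp2c families, the histocompatibility genes and mitochondrial genes with nuclear copies, and of overlapping or antisense genes, may be shared, so such genes are uncertain. Alternatives covered the pseudocount (0.1, 5), the filter, scaling (median of ratios, quantile), the libraries in the fit, a replicate block, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library; fits without sex-linked and mitochondrial genes and without the RGF day 3 and virus libraries were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 did the rest.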

Results

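Mouse hepatocyte organoids, which are liver cells kept growing as cell clusters in culture, were profiled by sequencing of poly(A)-selected RNA together with freshly isolated mouse hepatocytes. The 45 libraries formed 15 groups of 3 replicates, and the title of the series gives as its purpose the making of mature hepatocyte organoids for work on liver metabolism. The growth medium, called +GF here, held EGF, HGF, FGF7 and FGF10 beside Wnt pathway activators (RSPO1 conditioned medium and CHIR99021), the TGF-beta receptor inhibitor A83-01 and a Rho inhibitor. A second medium, called RGF, left out the growth factors and used another basal medium, and it was sampled on days 3, 6 and 12 after the switch. RGF was also given with 10 nM triiodothyronine (T3, the active thyroid hormone) on the same days, with T3 and 200 nM dexamethasone (DEX, a synthetic glucocorticoid) on the same days, and with dexamethasone alone on day 6. The +GF group has no day in the labels, so no comparison with it is matched in time. One group spent 6 days in RGF with T3 and then 6 days back in +GF, and is called returned organoids. Another pair of groups, in +GF and in RGF with T3, received an adeno-associated virus carrying N-terminally truncated beta-catenin behind a hepatocyte promoter and was collected on day 6. Each library held 16159953 to 47010541 recovered reads (median 28353219), with the lowest totals in T3 medium with truncated beta-catenin (16159953 to 17729160). The table held 16625 genes, of which 13248 reached 1 CPM (scaled to the authors' effective library size) in at least 3 libraries and were tested. Levels are given in CPM as mean ± SD of 3 libraries, and differences as log2 fold change ± SE on the scale of log2(CPM + 1), which understates the change of genes at low level and is written log2 or follows the words at, gave or by. Nothing in the labels says whether the 3 replicates of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. Replicates lay so close together that 5783 to 11074 genes passed the test in each pairwise comparison, and the counts of genes changed by at least 2-fold depend on the pseudocount in most comparisons. For a gene list, the numbers are its measured members that passed the test in each direction, their median log2 fold change and the camera p adjusted over the lists of that comparison, written FDR; the members counted adjusted over the list alone are added where they differ.

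The levels of several genes that marked some of the groups stand here because they move with gene groups described later. The reporter gene Tdtomato measured 986 ± 15.8 CPM in RGF on day 3 and 9.80 ± 0.45 CPM in +GF with truncated beta-catenin, and 0.0446 ± 0.023 CPM in +GF. Cre, a recombinase gene absent from the normal mouse genome, measured 5.91 ± 0.36 CPM in RGF on day 3. Xist, the RNA that silences an X chromosome in female cells, measured 98.4 ± 0.68 CPM in T3 medium with truncated beta-catenin and 0.0189 ± 0.033 CPM without it; in +GF it measured 6.45, 2.18 and 2.53 CPM in replicates 1, 2 and 3 with truncated beta-catenin and 0.0224 ± 0.020 CPM without it. Ddx3y, a gene of the Y chromosome, measured 0.159 ± 0.10 and 114 ± 1.2 CPM in T3 medium with and without it. Nos2, the inducible nitric oxide synthase, stood at 79.5 ± 2.5, 79.3 ± 5.3 and 141 ± 1.0 CPM in RGF on days 3, 6 and 12, at 199 ± 8.0 and 94.1 ± 1.5 CPM with truncated beta-catenin in +GF and in T3 medium, and at 0.30 ± 0.12 CPM in +GF and 0.934 ± 0.23 CPM in T3 medium on day 6. The chemokine gene Cxcl5 measured 529.7 ± 56.8, 297 ± 15.8 and 329 ± 5.2 CPM in RGF against 4.19 ± 1.2 CPM in +GF. Collagen gene Col1a1 measured 18.2 ± 1.3, 4.70 ± 1.4 and 18.7 ± 2.8 CPM in RGF, 53.6 ± 32.6 CPM in +GF with truncated beta-catenin and 0.881 ± 0.23 CPM in +GF. The mitochondrial transcript mt-Atp6 stood at 6.69 ± 0.82 and 6.45 ± 1.5 CPM with truncated beta-catenin in T3 medium and +GF, against 692 ± 27.7 and 424 ± 74.7 CPM without it. These genes, apart from those also named under the comparisons, were chosen after their values were seen.

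**Figure D1:**
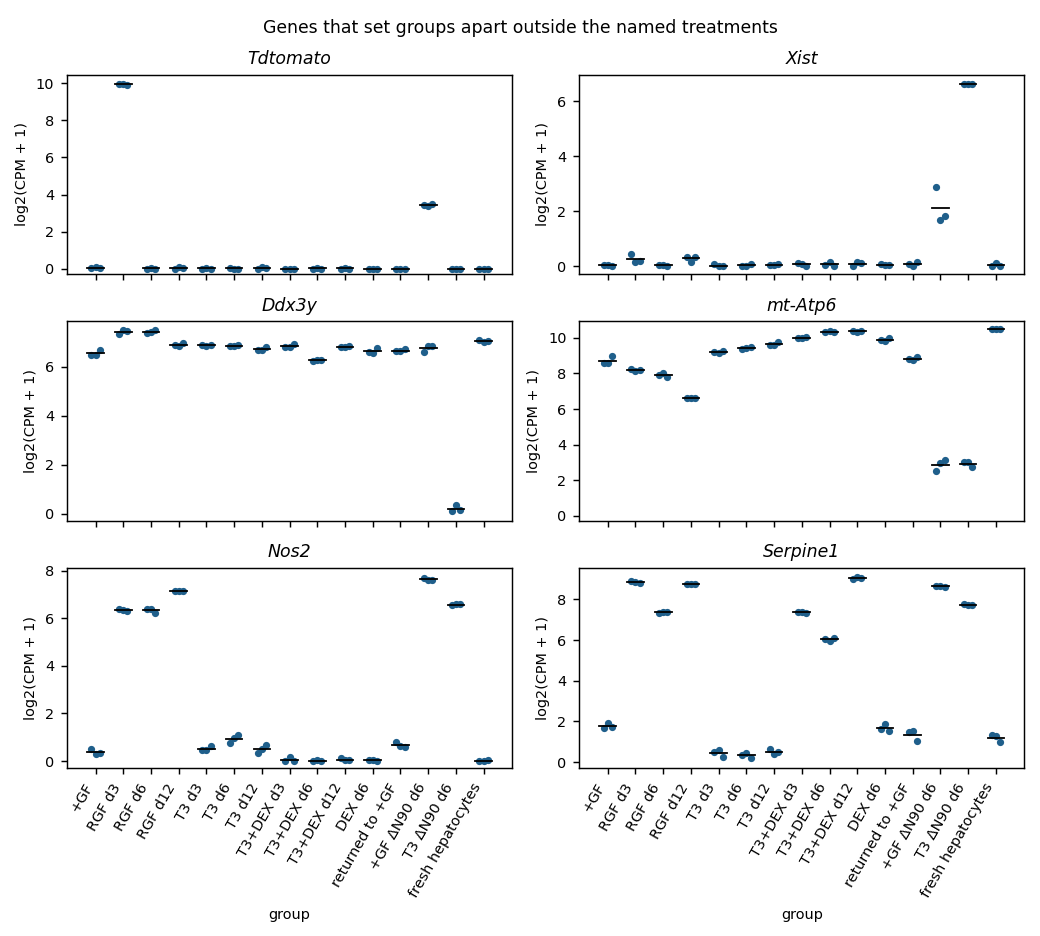
Level of 6 genes in each library, as log2(CPM + 1) on the vertical axis, by group on the horizontal axis; points are libraries and the bar is their mean (n = 3). Tdtomato is highest in RGF on day 3 (986 ± 15.8 CPM), Xist in T3 medium with truncated beta-catenin (98.4 ± 0.68 CPM), and Nos2 in +GF with truncated beta-catenin (199 ± 8.0 CPM).

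Organoids in growth medium kept albumin mRNA near the level of hepatocytes but held much less of the mRNA for hepatocyte metabolism, and more of the mRNA of fetal liver, bile duct and cytoskeletal genes. The albumin gene Alb (chromosome 5, 90460897 to 90476602 in mm10) stood at 97156 ± 1286 CPM against 82655 ± 867 (log2 0.23 ± 0.023). Under quantile normalization top genes give 0. By contrast Cyp2e1, a pericentral P450, stood at 1.24 ± 0.43 CPM against 7483 ± 41.5 (log2 -11.73 ± 0.21). The gluconeogenic gene Pck1 stood at 1.49 ± 0.71 CPM against 7308 ± 73.0 (log2 -11.56 ± 0.13) and Car3, a carbonic anhydrase gene, stood at 0.263 ± 0.071 CPM against 1642 ± 38.4 (log2 -10.35 ± 0.15). The pheromone carrier genes Mup7 and Mup14, whose reads may be shared within their family and are uncertain, were lower as well, with log2 fold changes of -11.81 ± 0.23 and -10.96 ± 0.17. The imprinted transcript H19 (chromosome 7, 142575529 to 142578143) stood at 10983 ± 337 CPM against 12.7 ± 5.6 (log2 9.74 ± 0.14), and Afp, the fetal alpha-fetoprotein gene (chromosome 5, 90490737 to 90508907), stood at 1787 ± 12.5 CPM against 3.34 ± 1.1 (log2 8.72 ± 0.091). Vim, S100a6 and Igfbp6 were higher by 8.23 ± 0.072, 8.16 ± 0.10 and 8.89 ± 0.088 on the log2 scale.

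For urea cycle and amino acid catabolism 36 of 36 were lower (median -4.24, FDR = 2.6e-21), with Bhmt and Pah at -9.04 ± 0.12 and -7.23 ± 0.047. Among bile acid genes 25 of 25 were lower (median -4.05, FDR = 4.2e-15), and the uptake transporters Slco1a1 and Slco1b2 gave -8.88 ± 0.16 and -8.58 ± 0.10. Of the P450 and phase II list 2 of 58 were higher and 55 lower (median -3.85, FDR = 3.3e-20), including Cyp1a2 at -9.46 ± 0.083 and Cyp2f2 at -8.85 ± 0.12. Zonation genes were lower on both sides of the lobule: 3 of 26 were higher and 23 lower (median -4.22, FDR = 2.1e-09) for the pericentral list, and 3 of 28 were higher and 23 lower (median -4.38, FDR = 4.9e-10) for the periportal list, where Igf1 gave -9.34 ± 0.11 and Etnppl -7.36 ± 0.10. In fatty acid oxidation 1 of 32 were higher and 31 lower (median -2.54, FDR = 1.7e-15), and in oxidative phosphorylation 37 of 37 were lower (median -1.39, FDR = 2.1e-13). Turning to lists that were higher, 13 of 14 were higher and 1 lower (median 4.82, FDR = 1.2e-07) in fetal and progenitor liver, and 18 of 21 were higher and 1 lower (median 3.10, FDR = 3.0e-06) among bile duct (cholangiocyte) markers, with Spp1 and Sox4 at 7.73 ± 0.066 and 6.40 ± 0.15. In the growth factor and ERK response 22 of 24 were higher and 2 lower (median 3.44, FDR = 3.6e-09), with Plaur and Hbegf at 5.87 ± 0.12 and 5.59 ± 0.11. In the YAP and cytoskeleton list 25 of 29 were higher and 2 lower (median 2.67, FDR = 9.5e-11). Limma called 11074 genes (5682 higher, 5392 lower), 4680 by at least 2-fold, and named genes said to differ had an adjusted p of at most 9.4e-13 (limma).

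Each culture was set against freshly isolated hepatocytes by a correlation over all tested genes and by the share of their main transcripts. Spearman correlation across genes, which are not replicates, with the hepatocyte mean was 0.776 ± 0.00013 in +GF, 0.847 ± 0.0018, 0.875 ± 0.0042 and 0.843 ± 0.00019 in RGF on days 3, 6 and 12, and 0.855 ± 0.0004, 0.887 ± 0.00039 and 0.896 ± 0.0002 with T3. With T3 and dexamethasone it was 0.875 ± 0.00049, 0.886 ± 0.00043 and 0.881 ± 0.0005, with dexamethasone alone 0.906 ± 9.5e-05, in returned organoids 0.771 ± 0.0016, and with truncated beta-catenin 0.776 ± 0.0018 in +GF and 0.857 ± 0.00036 in T3 medium. The 100 genes highest in hepatocytes took 44.5 ± 0.065% of the total there, 43.6 ± 0.15% in +GF, 41.3 ± 0.45%, 37.0 ± 0.29% and 29.0 ± 0.046% in RGF, 47.9 ± 0.063%, 42.0 ± 0.038% and 32.9 ± 0.052% with T3, and 52.7 ± 0.051%, 43.6 ± 0.087% and 37.2 ± 0.13% with T3 and dexamethasone. It was 47.8 ± 0.06% with dexamethasone alone, 42.9 ± 0.09% in returned organoids, and 39.6 ± 0.14% and 34.0 ± 0.14% with truncated beta-catenin in +GF and T3 medium. An exact two-sided permutation test against +GF gave p = 0.1, the smallest that 3 against 3 allows, for each group but the correlation of +GF with truncated beta-catenin (p = 1) and the share with T3 and dexamethasone on day 6 (p = 0.8).

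**Figure D2:**
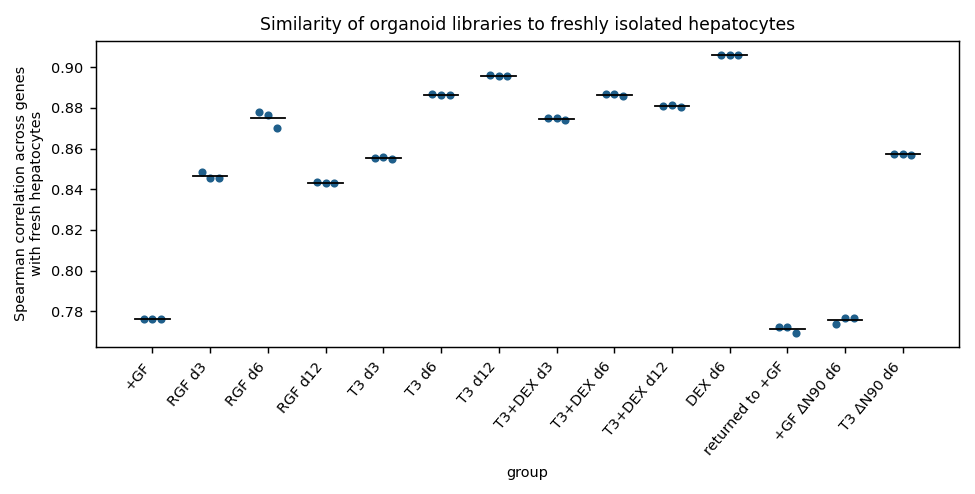
Spearman correlation across genes between each organoid library and the mean of freshly isolated hepatocytes (vertical axis) by group (horizontal axis); points are libraries and the bar is their mean (n = 3). Means run from 0.771 in returned organoids to 0.906 with dexamethasone alone on day 6.

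RGF was compared with growth medium first on day 3. Fetal and growth factor genes were lower then, and genes of hepatocyte metabolism and the acute phase higher. Culture is not separated from medium, as these RGF libraries held Tdtomato at 986 CPM. H19 fell from 10983 ± 337 to 7.75 ± 1.5 CPM (log2 -10.31 ± 0.14) and Afp fell from 1787 ± 12.5 to 55.7 ± 3.5 CPM (log2 -4.98 ± 0.091). Nrk, Bex1 and S100a6 fell (log2 -6.66 ± 0.10, -6.60 ± 0.084 and -6.20 ± 0.10), and Krt20 fell from 87.1 ± 3.9 to 0.645 ± 0.20 CPM (log2 -5.75 ± 0.10). Serpine1, encoding the plasminogen activator inhibitor PAI-1 (chromosome 5, 137061504 to 137072268), rose from 2.46 ± 0.30 to 463 ± 9.0 CPM (log2 7.07 ± 0.092), and Pigr, the polymeric immunoglobulin receptor gene, rose from 29.8 ± 0.91 to 3439.8 ± 169.8 CPM (log2 6.80 ± 0.037). Cxcl5 and Duox2 rose (log2 6.70 ± 0.12 and 6.43 ± 0.093). In the fetal and progenitor list 2 of 14 rose and 12 fell (median -2.87, FDR = 1.3e-06), and in the growth factor and ERK response 2 of 24 rose and 20 fell (median -1.90, FDR = 1.0e-06). Plaur and Myc gave -4.82 ± 0.12 and -3.68 ± 0.10. Among hepatocyte transcription factors 14 of 21 rose and 4 fell (median 0.68, FDR = 0.0014); the lipid-sensing receptor Ppara and the bile acid receptor Nr1h4 rose by 2.86 ± 0.051 and 2.56 ± 0.044. Bile acid genes rose nearly throughout (24 of 25 rose and 0 fell, median 1.06, FDR = 2.1e-09), with Slco1b2, Akr1d1 and Cyp7b1 at 3.87 ± 0.10, 3.51 ± 0.057 and 3.41 ± 0.11.

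For P450 and phase II genes 38 of 58 rose and 11 fell (median 0.77, FDR = 4.8e-06). Here Cyp3a11, a main drug-metabolising P450, rose from 268 ± 13.6 to 4972 ± 183 CPM (log2 4.21 ± 0.042). Of pericentral genes 15 of 26 rose and 5 fell (median 0.38, FDR = 0.014), with Gstm3, Glul and Cyp2a5 at 3.08 ± 0.051, 2.78 ± 0.044 and 2.59 ± 0.061 and Cyp1a2 (chromosome 9, 57676937 to 57683703) rose from 0.789 ± 0.10 to 22.3 ± 0.14 CPM (log2 3.70 ± 0.083). In urea cycle and amino acid catabolism 29 of 36 rose and 3 fell (median 1.16, FDR = 6.1e-09), and in fatty acid oxidation 25 of 32 rose and 3 fell (median 0.72, FDR = 1.0e-06), where Hmgcs2, the ketogenic synthase, gave 2.84 ± 0.040. Cholesterol synthesis went down, as 5 of 25 rose and 20 fell (median -0.81, FDR = 1.0e-04), with Fdps, Idi1 and the rate-limiting reductase Hmgcr at -1.75 ± 0.036, -1.64 ± 0.083 and -1.70 ± 0.031. Proliferation genes were higher (29 of 42 rose and 6 fell, median 0.71, FDR = 0.012). Mki67 rose from 5.20 ± 0.52 to 29.7 ± 0.95 CPM (log2 2.31 ± 0.11). Top2a gave 2.27 ± 0.12 and Hmmr 2.38 ± 0.13, while Ccnd1 fell (-2.47 ± 0.062). In the acute phase list 22 of 24 rose and 2 fell (median 1.43, FDR = 1.6e-10). Saa1, Saa2 and Saa3 gave 4.93 ± 0.046, 5.70 ± 0.037 and 4.76 ± 0.047 and Hamp, encoding hepcidin, at -4.79 ± 0.11. In the interferon list 21 of 23 rose and 0 fell (median 1.56, FDR = 7.4e-08). Fibroblast markers were higher (15 of 17 rose and 1 fell, median 2.02, FDR = 1.9e-04), with Col3a1, Dcn and Col1a1 at 4.88 ± 0.18, 3.63 ± 0.14 and 3.36 ± 0.20. YAP and cytoskeletal genes fell (2 of 29 rose and 26 fell, median -1.63, FDR = 2.1e-11), as did bile duct markers (4 of 21 rose and 14 fell, median -0.83, FDR = 0.012). By limma 10661 genes passed (5387 higher, 5274 lower), 3234 by at least 2-fold, with adjusted p of at most 2.0e-19 for those named.

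By day 6 in RGF metabolic genes were higher and growth factor and stress genes lower than in +GF. Bhmt, a methyltransferase of methionine metabolism, rose from 1.74 ± 0.71 to 1149 ± 15.3 CPM (log2 8.75 ± 0.12), and Cyp8b1, which sets the ratio of bile acids, rose from 0.695 ± 0.040 to 165 ± 4.7 CPM (log2 6.61 ± 0.093). Pigr, Slco1b2 and Cyp1a2 rose (log2 6.87 ± 0.037, 6.20 ± 0.10 and 5.92 ± 0.083). H19, Afp, S100a6 and Nrk fell (log2 -8.77 ± 0.14, -6.77 ± 0.091, -6.94 ± 0.10 and -6.44 ± 0.10). Bile acid genes (24 of 25 rose and 1 fell, median 1.99, FDR = 1.3e-12), urea cycle and amino acid genes (29 of 36 rose and 5 fell, median 1.94, FDR = 1.7e-11) and P450 genes (44 of 58 rose and 9 fell, median 1.41, FDR = 1.5e-10) rose as groups. For the pericentral list 17 of 26 rose and 3 fell (median 1.91, FDR = 7.9e-06). For gluconeogenesis and glycogen 13 of 17 rose and 2 fell (median 1.61, FDR = 1.5e-05), with the glucose-releasing phosphatase G6pc at 3.76 ± 0.084 and Igfbp1 at -3.67 ± 0.027. Every measured interferon gene rose: 23 of 23 rose (median 1.65, FDR = 4.5e-09). Nos2, high in RGF without hormones on each day, gave 5.95 ± 0.088. Growth factor and ERK genes (2 of 24 rose and 22 fell, median -2.67, FDR = 3.2e-09), proliferation genes (5 of 42 rose and 28 fell, median -0.36, FDR = 0.022) and integrated stress genes (5 of 23 rose and 16 fell, median -0.88, FDR = 0.0032) fell. Plaur, Ccnd1, Phgdh and Psat1 gave -5.20 ± 0.12, -4.26 ± 0.062, -5.02 ± 0.12 and -4.50 ± 0.14; Mki67 itself measured 5.20 ± 0.52 CPM in +GF and 4.95 ± 0.44 CPM here. The genes called by limma numbered 10647 (5272 higher, 5375 lower), 3444 by at least 2-fold, with adjusted p of 2.3e-30 or less (limma) for the named genes.

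After 12 days in RGF, interferon genes had the greatest median rise of the tested lists, while fetal genes were low. In the interferon list 23 of 23 rose (median 3.16, FDR = 8.4e-16), with Ifit3, Rsad2, Oasl2 and Ifit1 at 7.23 ± 0.15, 6.72 ± 0.13, 6.58 ± 0.13 and 5.83 ± 0.11. Cyp1a2 rose from 0.789 ± 0.10 to 485 ± 5.3 CPM (log2 8.09 ± 0.083). Cyp2a5, Serpine1 and Bhmt rose (log2 7.30 ± 0.061, 6.97 ± 0.092 and 6.87 ± 0.12). H19, Igf2, Nrk and Afp fell (log2 -9.45 ± 0.14, -9.10 ± 0.15, -6.76 ± 0.10 and -6.01 ± 0.091). Pericentral genes (18 of 26 rose and 3 fell, median 2.15, FDR = 5.6e-07) and P450 genes (46 of 58 rose and 9 fell, median 1.94, FDR = 4.2e-14) were higher than in +GF. Glucocorticoid target genes were higher without added dexamethasone: 20 of 31 rose and 8 fell (median 0.46, FDR = 0.0048). In the growth factor and ERK response 3 of 24 rose and 20 fell (median -1.76, FDR = 6.4e-08). Hbegf, Ereg and Spry2 gave -3.52 ± 0.11, -3.47 ± 0.14 and -3.33 ± 0.12. Macrophage markers also rose (9 of 11 rose and 0 fell, median 0.93, FDR = 0.0023): Cd68, Lyz2 and Cd14 gave 5.88 ± 0.11, 3.00 ± 0.14 and 0.91 ± 0.067. Over all genes limma called 10022 (4981 higher, 5041 lower), 2482 by at least 2-fold; adjusted p-values of the named genes reached 3.2e-16 (limma). Differences between the days were not tested for the RGF comparisons, so no gene or list is said to differ by day.

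Adding T3 to RGF was compared at matched days. On day 3 the hormone's own targets and lipid synthesis genes were higher, and acute phase, interferon and fibroblast genes lower, than in RGF alone. Dio1, the liver deiodinase of thyroid hormone (chromosome 4, 107291465 to 107307169), rose from 28.1 ± 2.5 to 430.4 ± 5.4 CPM (log2 3.90 ± 0.086), and Thrsp, named for its response to thyroid hormone (chromosome 7, 97412938 to 97417730), rose from 12.6 ± 0.90 to 44.0 ± 0.36 CPM (log2 1.73 ± 0.064). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 0.168 ± 0.069 to 21.7 ± 2.1 CPM (log2 4.28 ± 0.084), and the thyroid list as a whole had 12 of 20 rose and 6 fell (median 0.70, FDR = 0.015, adjusted p = 0.096 with an estimated correlation). Every measured gene of cholesterol synthesis rose (25 of 25 rose, median 0.82, FDR = 9.6e-12), with Idi1, Hmgcr and Fdps at 2.12 ± 0.083, 1.97 ± 0.031 and 1.87 ± 0.036. In lipogenesis 19 of 27 rose and 3 fell (median 0.50, FDR = 6.8e-05), including Fads2 and Gck, the liver glucokinase, at 2.49 ± 0.034 and 2.34 ± 0.11. H19 rose from 7.75 ± 1.5 to 4537 ± 44.2 CPM (log2 9.03 ± 0.14). Col4a3 and Hamp rose (log2 6.17 ± 0.12 and 6.00 ± 0.11). For the fetal list 11 of 14 rose and 1 fell (median 1.86, FDR = 2.2e-05).

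Periportal genes were higher with T3 on day 3 (20 of 28 rose and 6 fell, median 0.37, FDR = 0.018, adjusted p = 0.21 with an estimated correlation), and Cyp2f2 (chromosome 7, 27119909 to 27133660) rose from 2.78 ± 0.28 to 54.8 ± 1.4 CPM (log2 3.89 ± 0.12). Tat, Pck1 and G6pc gave 2.52 ± 0.027, 2.39 ± 0.13 and 1.99 ± 0.084. Serpine1, Cxcl5, Duox2 and Pigr fell (log2 -8.41 ± 0.092, -7.17 ± 0.12, -6.61 ± 0.093 and -5.96 ± 0.037). Interferon genes (4 of 23 rose and 19 fell, median -0.85, FDR = 3.4e-04) and acute phase genes (7 of 24 rose and 16 fell, median -0.71, FDR = 4.1e-04) fell. Ifi44, Ifit1 and Saa3 gave -2.53 ± 0.13, -2.31 ± 0.11 and -4.61 ± 0.047. Fibroblast markers were lower too (1 of 17 rose and 14 fell, median -1.73, FDR = 3.8e-05), with Col3a1 at -4.77 ± 0.18. The RGF libraries of this day are those with Tdtomato at 986 ± 15.8 CPM. Mki67 and Sox9 fell by log2 fold changes of -1.40 ± 0.11 and -2.32 ± 0.11. Limma called 9895 genes (5143 higher, 4752 lower), 2060 by at least 2-fold, and named genes said to differ had an adjusted p of at most 1.0e-14 (limma).

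On day 6 T3 went with higher periportal genes, like DEX alone (median 1.75), and lower pericentral genes. Cyp2f2 rose from 4.65 ± 0.87 to 252 ± 3.1 CPM (log2 5.50 ± 0.12), and Cyp1a2 fell from 107 ± 3.9 to 1.34 ± 0.32 CPM (log2 -5.54 ± 0.083). In the periportal list 22 of 28 rose and 5 fell (median 1.00, FDR = 5.1e-06), and Pck1 gave 5.34 ± 0.13. Of pericentral genes 5 of 26 rose and 18 fell (median -0.85, FDR = 9.6e-05). Of Wnt targets 3 of 21 rose and 13 fell (median -0.30, FDR = 0.025), where Tbx3 gave -1.90 ± 0.080. Dio1 rose from 59.7 ± 4.8 to 786 ± 11.9 CPM (log2 3.70 ± 0.086), and the thyroid list had 10 of 20 rose and 6 fell (median 0.46, FDR = 0.03, adjusted p = 0.12 with an estimated correlation). Cholesterol synthesis (21 of 25 rose and 3 fell, 22 and 3 adjusted over the list alone, median 0.54, FDR = 3.1e-06) and lipogenesis (19 of 27 rose and 7 fell, median 0.53, FDR = 5.5e-04) rose. Idi1, Thrsp, Mlxipl and Fasn gave 1.59 ± 0.083, 3.06 ± 0.064, 2.10 ± 0.061 and 1.87 ± 0.031. For fatty acid oxidation 3 of 32 rose and 28 fell (median -0.69, FDR = 5.3e-08), with Cyp4a10, Hmgcs2 and Acox1 at -2.83 ± 0.092, -1.89 ± 0.040 and -1.70 ± 0.022. H19 and Col4a3 rose (log2 6.04 ± 0.14 and 5.94 ± 0.12), and Serpine1, Cxcl5, Duox2 and Pigr fell (log2 -7.04 ± 0.092, -6.51 ± 0.12, -6.03 ± 0.093 and -5.41 ± 0.037). Interferon genes fell (3 of 23 rose and 19 fell, median -1.02, FDR = 7.4e-05). By limma 9828 genes passed (5104 higher, 4724 lower), 1753 by at least 2-fold, with adjusted p of at most 3.1e-21 for those named.

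On day 12 the thyroid targets, the urea cycle and cholesterol synthesis were higher with T3, and interferon, glycolysis and growth factor genes lower. The thyroid list had 14 of 20 rose and 5 fell (median 0.83, FDR = 9.6e-04), with Dio1, Thrsp, Cyp7a1 and the thyroid hormone transporter Slc16a10 at 4.34 ± 0.086, 4.04 ± 0.064, 3.55 ± 0.084 and 2.86 ± 0.050. In urea cycle and amino acid catabolism 30 of 36 rose and 3 fell (median 1.19, FDR = 2.7e-14). Hal, Tat and Otc gave 4.18 ± 0.066, 3.27 ± 0.027 and 2.86 ± 0.049. Pck1 (chromosome 2, 173153048 to 173159273) rose from 0.880 ± 0.084 to 100.4 ± 0.41 CPM (log2 5.75 ± 0.13). Periportal genes (22 of 28 rose and 5 fell, 23 and 5 adjusted over the list alone, median 1.10, FDR = 3.9e-07) and cholesterol synthesis (24 of 25 rose and 1 fell, median 1.00, FDR = 1.0e-12) rose. In the interferon list 0 of 23 rose and 22 fell (median -2.73, FDR = 7.0e-15), and Ifit3 gave -6.60 ± 0.15. Serpine1, Cxcl5 and Nos2 fell (log2 -8.24 ± 0.092, -6.75 ± 0.12 and -6.65 ± 0.088). Glycolysis (1 of 17 rose and 13 fell, median -0.99, FDR = 8.6e-07), YAP and cytoskeletal genes (2 of 29 rose and 23 fell, median -0.55, FDR = 1.3e-06), and growth factor and ERK genes (3 of 24 rose and 17 fell, median -0.61, FDR = 2.9e-04) fell. Hk2, Ankrd1 and Plaur gave -3.20 ± 0.12, -3.19 ± 0.088 and -3.23 ± 0.12. Alb fell from 39714 ± 111 to 9361 ± 87.2 CPM (log2 -2.08 ± 0.023). The genes called by limma numbered 9592 (4952 higher, 4640 lower), 1898 by at least 2-fold, with adjusted p of 3.2e-26 or less (limma) for the named genes.

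The T3 effect as measured differed between day 12 and day 3, by the interaction test over the 4 groups. RGF alone on day 3, with Tdtomato at 986 CPM, is one of them, so culture is not separated from day. Saa2 and Thrsp had a more positive effect on day 12, by 6.26 ± 0.053 and 2.31 ± 0.090 on the log2 scale, and H19, Cxcl10, Hamp, Ifit3 and Alb a more negative one, by -7.38 ± 0.20, -5.76 ± 0.14, -5.23 ± 0.16, -5.16 ± 0.21 and -2.34 ± 0.032. Of the lists it was more negative for interferon genes, with a median difference of -2.17 (FDR = 1.3e-11), and fetal liver, with -1.63 (FDR = 1.1e-05). It was more positive for urea cycle and amino acid catabolism, with 1.30 (FDR = 2.8e-19), and periportal genes, with 0.90 (FDR = 3.0e-08). Limma called 8823 genes (4262 more positive and 4561 more negative), with adjusted p-values of at most 3.9e-20 for those named.

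The whole switch was compared as RGF with T3 on day 6 against growth medium. Organoids then held more mRNA for hormone response, amino acid, bile acid and lipid metabolism and less for growth factor response, cytoskeleton and fetal liver. Dio1 rose from 5.80 ± 0.30 to 786 ± 11.9 CPM (log2 6.86 ± 0.086), and Cyp2f2 rose from 1.5 ± 0.55 to 252 ± 3.1 CPM (log2 6.69 ± 0.12). Gck, Akr1d1 and Thrsp rose (log2 6.60 ± 0.11, 6.53 ± 0.057 and 6.39 ± 0.064), while Igfbp3, Ly6d, Nrk and S100a6 fell (log2 -6.70 ± 0.060, -6.05 ± 0.12, -5.99 ± 0.10 and -5.83 ± 0.10). In urea cycle and amino acid catabolism 34 of 36 rose and 1 fell, 34 and 2 adjusted over the list alone (median 2.33, FDR = 1.4e-22). Pah, Prodh, Bhmt and Arg1 gave 4.72 ± 0.047, 4.30 ± 0.069, 4.26 ± 0.12 and 4.25 ± 0.044. Bile acid genes rose (22 of 25 rose and 2 fell, median 2.45, FDR = 6.6e-15), with Cyp7a1, Cyp8b1 and the bile salt importer Slc10a1 at 5.80 ± 0.084, 4.89 ± 0.093 and 4.79 ± 0.070. Periportal genes (24 of 28 rose and 4 fell, median 1.40, FDR = 4.2e-11), lipogenesis (23 of 27 rose and 1 fell, 24 and 1 adjusted over the list alone, median 1.33, FDR = 3.3e-11) and the thyroid list (15 of 20 rose and 1 fell, median 1.52, FDR = 7.7e-09) rose. G6pc and Pck1 gave 5.45 ± 0.084 and 4.22 ± 0.13. For oxidative phosphorylation 37 of 37 rose (median 0.74, FDR = 1.7e-13), and for the interferon response 20 of 23 rose and 0 fell (median 0.90, FDR = 4.7e-06). Growth factor and ERK genes fell (0 of 24 rose and 23 fell, median -2.60, FDR = 2.0e-13). Plaur, Ereg, Areg and Hbegf gave -5.17 ± 0.12, -3.85 ± 0.14, -3.79 ± 0.12 and -3.73 ± 0.11. YAP and cytoskeletal genes (2 of 29 rose and 24 fell, median -1.60, FDR = 3.3e-13), fetal genes (1 of 14 rose and 11 fell, median -1.82, FDR = 8.5e-06) and bile duct markers (3 of 21 rose and 14 fell, median -0.61, FDR = 4.5e-04) fell as well, with Vim, Thbs1, Hmga2 and Spp1 at -5.03 ± 0.072, -3.79 ± 0.16, -4.90 ± 0.12 and -3.63 ± 0.066. Over all genes limma called 9293 (4736 higher, 4557 lower), 2013 by at least 2-fold; adjusted p-values of the named genes reached 9.2e-25 (limma).

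Time in T3 medium was followed from day 3 to day 12. Both zonation lists and bile acid genes rose, and plasma protein, proliferation and fetal genes fell. Sult1e1, an estrogen sulfotransferase gene, rose from 0.867 ± 0.23 to 213 ± 6.3 CPM (log2 6.84 ± 0.18), and Slco1a4 and Gstm3 rose (log2 5.31 ± 0.081 and 5.28 ± 0.051). H19, Hamp, Cdh17 and Afp fell (log2 -6.52 ± 0.14, -5.01 ± 0.11, -4.72 ± 0.11 and -4.53 ± 0.091). Among plasma proteins 6 of 37 rose and 31 fell (median -0.83, FDR = 6.2e-22), and Alb fell from 92535 ± 818 to 9361 ± 87.2 CPM (log2 -3.31 ± 0.023). Of pericentral genes 20 of 26 rose and 3 fell (median 0.92, FDR = 5.5e-08), of periportal genes 18 of 28 rose and 6 fell, 18 and 7 adjusted over the list alone (median 0.66, FDR = 5.4e-06), and of Wnt targets 14 of 21 rose and 3 fell, 14 and 4 adjusted over the list alone (median 0.46, FDR = 0.025); Glul, Pck1 and Arg1 gave 2.06 ± 0.044, 4.19 ± 0.13 and 2.70 ± 0.044. Urea cycle and amino acid genes (32 of 36 rose and 1 fell, median 1.32, FDR = 9.6e-25), bile acid genes (23 of 25 rose and 1 fell, median 0.95, FDR = 9.0e-17) and oxidative phosphorylation (37 of 37 rose, median 0.58, FDR = 9.6e-18) rose. In the growth factor and ERK response 1 of 24 rose and 23 fell (median -1.09, FDR = 2.3e-10), and in proliferation 1 of 42 rose and 35 fell (median -0.52, FDR = 2.1e-05). Egr1 and Mki67 gave -2.47 ± 0.064 and -1.03 ± 0.11. Limma called 7986 genes (4123 higher, 3863 lower), 961 by at least 2-fold, and named genes said to differ had an adjusted p of at most 1.8e-10 (limma).

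Dexamethasone added to T3 medium was compared with T3 alone at matched days. On day 3 glucocorticoid targets and glucose-producing, urea cycle and respiratory genes rose, and cell cycle and interferon genes fell. In the glucocorticoid list 30 of 31 rose and 1 fell (median 2.02, FDR = 1.4e-30): Fkbp5, a co-chaperone gene and direct receptor target (chromosome 17, 28399094 to 28517527), rose from 42.4 ± 3.4 to 927 ± 19 CPM (log2 4.42 ± 0.041), and Tsc22d3, Per1 and Tat gave 2.74 ± 0.062, 1.32 ± 0.067 and 2.46 ± 0.027. Pck1 rose from 4.63 ± 1.1 to 268 ± 4.2 CPM (log2 5.60 ± 0.13), and Slc2a2, the liver glucose transporter gene, rose from 3.41 ± 0.81 to 265 ± 6.6 CPM (log2 5.93 ± 0.14). For gluconeogenesis and glycogen 16 of 17 rose and 0 fell (median 1.41, FDR = 1.2e-19). Sult1e1, Serpine1 and Cyp17a1 rose (log2 8.07 ± 0.18, 6.92 ± 0.092 and 6.64 ± 0.12). In urea cycle and amino acid catabolism 32 of 36 rose and 3 fell (median 1.61, FDR = 2.3e-30), with Bhmt and Cps1 at 3.97 ± 0.12 and 2.81 ± 0.021. Periportal genes rose too (21 of 28 rose and 5 fell, median 1.05, FDR = 1.7e-12). Glycolysis (15 of 17 rose and 0 fell, median 1.00, FDR = 1.6e-12) and oxidative phosphorylation (37 of 37 rose, median 0.48, FDR = 1.3e-15) rose. Pfkfb3 gave 2.19 ± 0.093 and Cox6c at 0.91 ± 0.055. Thrsp gave 2.92 ± 0.064.

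Cell cycle genes fell on day 3 with dexamethasone (3 of 42 rose and 33 fell, 3 and 34 adjusted over the list alone, median -0.77, FDR = 4.8e-07). Mki67, Tpx2 and Top2a gave -1.89 ± 0.11, -1.40 ± 0.16 and -1.39 ± 0.12 but Rrm2 at 1.53 ± 0.085. Spp1, encoding osteopontin, fell from 798 ± 5.7 to 34.8 ± 1.4 CPM (log2 -4.48 ± 0.066), and Hamp, Cybb and Serpina6 fell (log2 -4.71 ± 0.11, -4.24 ± 0.10 and -3.97 ± 0.13); Serpina6 encodes corticosteroid-binding globulin. Interferon genes fell (2 of 23 rose and 20 fell, 2 and 21 adjusted over the list alone, median -0.81, FDR = 3.9e-09). Ifi44, Isg15 and Gbp3 gave -2.40 ± 0.13, -2.15 ± 0.12 and -2.11 ± 0.12 and Usp18 at 2.02 ± 0.085. In total 7226 genes passed in limma (3337 higher, 3889 lower), 960 by at least 2-fold, and the highest adjusted p of a named gene that passed was 1.5e-10 (limma).

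Day 6 gave the same direction for glucocorticoid, glycolytic and respiratory lists, and lower acute phase and interferon genes. The glucocorticoid list had 29 of 31 rose and 2 fell (median 2.21, FDR = 9.8e-19), with Fkbp5, Angptl4 and Gadd45g at 4.83 ± 0.041, 4.58 ± 0.063 and 4.47 ± 0.12. Sult1e1 and Apoa4 rose (log2 8.51 ± 0.18 and 5.86 ± 0.078), and Cybb and Cxcl1 fell (log2 -5.18 ± 0.10 and -3.77 ± 0.072). Gluconeogenesis and glycogen (16 of 17 rose and 0 fell, median 1.37, FDR = 1.5e-11), glycolysis (16 of 17 rose and 0 fell, median 1.52, FDR = 3.1e-12), oxidative phosphorylation (37 of 37 rose, median 0.83, FDR = 2.7e-20) and fatty acid oxidation (25 of 32 rose and 7 fell, median 0.55, FDR = 7.2e-06) rose. Slc16a3, Pkm and Pdk4 gave 3.00 ± 0.10, 2.45 ± 0.055 and 3.26 ± 0.091. In the interferon list 1 of 23 rose and 21 fell, 1 and 22 adjusted over the list alone (median -1.19, FDR = 1.7e-08), and in the acute phase list 7 of 24 rose and 15 fell (median -0.82, FDR = 7.3e-04). Steap4 gave -3.49 ± 0.024 and Serpina3n at 2.43 ± 0.026. Thrsp gave 2.14 ± 0.064. The genes called by limma numbered 8962 (4386 higher, 4576 lower), 1300 by at least 2-fold, with adjusted p of 3.6e-28 or less (limma) for the named genes.

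By day 12 glycolytic genes were all higher with dexamethasone and bile acid genes mostly lower. In glycolysis 17 of 17 rose (median 1.33, FDR = 2.8e-19), with Slc16a3, Hk2 and Pkm at 4.21 ± 0.10, 3.24 ± 0.12 and 3.10 ± 0.055. Among bile acid genes 4 of 25 rose and 20 fell (median -0.47, FDR = 1.6e-07), with Akr1c6, Slco1b2 and Cyp8b1 at -5.21 ± 0.13, -3.94 ± 0.10 and -1.82 ± 0.093. Cyp2e1 rose from 3.96 ± 0.83 to 220.5 ± 1.2 CPM (log2 5.50 ± 0.21). Serpine1 and Apoa4 rose (log2 8.54 ± 0.092 and 6.80 ± 0.078). The glucocorticoid list had 27 of 31 rose and 1 fell (median 2.03, FDR = 4.0e-21), with Fkbp5, Igfbp1 and Sgk1 at 4.56 ± 0.041, 4.07 ± 0.027 and 3.94 ± 0.10. Proliferation (5 of 42 rose and 32 fell, 5 and 33 adjusted over the list alone, median -0.56, FDR = 0.0013) and interferon genes (1 of 23 rose and 22 fell, median -0.90, FDR = 8.4e-09) fell. Dio1 and Thrsp gave -1.04 ± 0.086 and -0.24 ± 0.064, and Alb 2.11 ± 0.023. Over all genes limma called 7244 (3344 higher, 3900 lower), 1018 by at least 2-fold; adjusted p-values of the named genes reached 0.0011 (limma).

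Dexamethasone without T3 was compared with RGF alone on day 6. Glucocorticoid, periportal, urea cycle and cholesterol genes rose, and interferon and macrophage genes fell. Pck1 rose from 0.120 ± 0.15 to 131 ± 3.3 CPM (log2 6.89 ± 0.13), and Slc2a2 rose from 2.12 ± 0.73 to 442 ± 9.3 CPM (log2 7.18 ± 0.14). Sult1e1 rose from 0.0786 ± 0.069 to 724 ± 37.6 CPM (log2 9.39 ± 0.18). In the glucocorticoid list 24 of 31 rose and 6 fell (median 2.06, FDR = 7.6e-10), with Fkbp5, Sgk1 and Mfsd2a at 5.66 ± 0.041, 5.47 ± 0.10 and 4.67 ± 0.10. Urea cycle and amino acid genes (33 of 36 rose and 2 fell, 34 and 2 adjusted over the list alone, median 1.42, FDR = 1.8e-16), periportal genes (24 of 28 rose and 4 fell, median 1.75, FDR = 1.9e-10) and cholesterol synthesis (23 of 25 rose and 1 fell, median 0.89, FDR = 1.9e-10) rose. Sds, Hal and Hmgcr gave 4.64 ± 0.11, 3.29 ± 0.066 and 2.21 ± 0.031. For oxidative phosphorylation 35 of 37 rose and 0 fell (median 0.51, FDR = 1.3e-09), and for fetal liver 8 of 14 rose and 1 fell (median 1.48, FDR = 3.7e-04). H19 gave 5.95 ± 0.14. Cxcl5, Cybb, Neurl3 and Duox2 fell (log2 -8.06 ± 0.12, -6.53 ± 0.10, -6.20 ± 0.10 and -5.99 ± 0.093). In the interferon list 3 of 23 rose and 20 fell (median -1.62, FDR = 7.6e-10), and in the macrophage list 0 of 11 rose and 9 fell (median -0.65, FDR = 0.013). Cd14 and Cd68 gave -4.31 ± 0.067 and -2.90 ± 0.11. Dio1 gave -3.04 ± 0.086. Limma called 9722 genes (5065 higher, 4657 lower), 1897 by at least 2-fold, and named genes said to differ had an adjusted p of at most 7.1e-26 (limma).

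Whether the T3 effect on day 6 differed with dexamethasone was tested over the 4 groups. With dexamethasone the T3 effect was more positive for Serpine1, Ndufa4l2, Cxcl5 and Dio1, by 11.40 ± 0.13, 7.42 ± 0.12, 6.47 ± 0.17 and 2.42 ± 0.12, and more negative for H19, Pck1 and Cyp2f2, by -8.46 ± 0.20, -2.97 ± 0.19 and -3.78 ± 0.17 on the log2 scale. Among lists it was more positive for glycolysis, with a median difference of 1.11 (FDR = 2.1e-11), and for fatty acid oxidation, with 0.82 (FDR = 7.0e-15), and more negative for periportal genes, with -1.20 (FDR = 7.4e-08), and for cholesterol synthesis, with -0.65 (FDR = 8.3e-10). By limma 8303 genes differed (3885 more positive and 4418 more negative), with adjusted p-values of at most 4.1e-18 for the named ones (limma). RGF alone on day 6, with Nos2 at 79.3 ± 5.3 CPM, is one of the 4 groups.

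Organoids returned to growth medium after 6 days with T3 were compared with organoids collected at the end of those 6 days. Metabolic genes fell and growth factor, cell cycle and fetal genes rose. Cyp2f2 fell from 252 ± 3.1 to 2.44 ± 0.53 CPM (log2 -6.21 ± 0.12), and Thrsp fell from 281 ± 2.9 to 2.74 ± 0.51 CPM (log2 -6.25 ± 0.064). Gck and Slco1b2 fell (log2 -6.60 ± 0.11 and -5.78 ± 0.10), and Igfbp3, Cdh17 and Ly6d rose (log2 6.87 ± 0.060, 5.56 ± 0.11 and 5.41 ± 0.12). In urea cycle and amino acid catabolism 2 of 36 rose and 34 fell (median -2.67, FDR = 2.1e-23), with Hpd and Mat1a at -5.39 ± 0.080 and -5.33 ± 0.051. Bile acid (2 of 25 rose and 22 fell, median -2.46, FDR = 1.9e-15), periportal (3 of 28 rose and 24 fell, median -2.21, FDR = 1.8e-12), P450 (9 of 58 rose and 41 fell, median -0.82, FDR = 6.3e-10) and thyroid genes (1 of 20 rose and 16 fell, median -1.26, FDR = 1.1e-08) fell, as did oxidative phosphorylation (37 of 37 fell, median -0.89, FDR = 1.4e-15). Acute phase genes fell (2 of 24 rose and 22 fell, median -1.59, FDR = 1.1e-14), with Saa2 and Orm2 at -5.01 ± 0.037 and -4.84 ± 0.026. Every measured growth factor and ERK gene rose (24 of 24 rose, median 2.09, FDR = 1.1e-14), and so did every proliferation gene (42 of 42 rose, median 1.41, FDR = 1.9e-13). Plaur and Mki67 gave 4.39 ± 0.12 and 2.38 ± 0.11. For fetal liver 12 of 14 rose and 0 fell (median 1.41, FDR = 1.6e-06), and Afp rose from 59.0 ± 1.2 to 1770.1 ± 21.6 CPM (log2 4.88 ± 0.091). For YAP and cytoskeletal genes 23 of 29 rose and 2 fell (median 1.11, FDR = 6.3e-10), with Vim at 4.07 ± 0.072. In total 9308 genes passed in limma (4481 higher, 4827 lower), 1975 by at least 2-fold, and the highest adjusted p of a named gene that passed was 1.3e-22 (limma).

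Against organoids kept in growth medium, the returned organoids differed in fewer genes than in the other pairwise comparisons, and the interferon and proliferation lists had the largest median changes of the tested lists. In the interferon list 23 of 23 rose (median 1.82, FDR = 4.4e-36), with Rsad2, Ifit3 and Ifit1 at 4.90 ± 0.13, 4.47 ± 0.15 and 4.25 ± 0.11. In the proliferation list 39 of 42 rose and 1 fell, 40 and 1 adjusted over the list alone (median 1.02, FDR = 3.6e-21): Mki67 rose from 5.20 ± 0.52 to 20.7 ± 1.3 CPM (log2 1.81 ± 0.11), and Rrm2 gave 1.74 ± 0.085. Acute phase genes were lower (3 of 24 rose and 20 fell, median -0.77, FDR = 6.4e-19), with Hamp and Saa1 at -2.71 ± 0.11 and -1.83 ± 0.046. Ugt3a2 and Fbln2 fell (log2 -3.63 ± 0.10 and -3.15 ± 0.11). YAP and cytoskeletal genes (2 of 29 rose and 20 fell, 3 and 21 adjusted over the list alone, median -0.49, FDR = 1.3e-11) and fatty acid oxidation (2 of 32 rose and 24 fell, 2 and 25 adjusted over the list alone, median -0.23, FDR = 6.1e-07) fell. For the thyroid list 10 of 20 rose and 5 fell, 11 and 5 adjusted over the list alone (median 0.21, FDR = 0.0011), with Dio1 at 3.01 ± 0.086, and for cholesterol synthesis 15 of 25 rose and 3 fell (median 0.20, FDR = 1.5e-05). Afp stood at 1770.1 ± 21.6 CPM against 1787 ± 12.5, and Dusp6, a feedback phosphatase of ERK signalling, at 124 ± 1.1 against 131 ± 13.1; neither passed the test. The genes called by limma numbered 5783 (2501 higher, 3282 lower), 407 by at least 2-fold, with adjusted p of 1.4e-17 or less (limma) for the named genes.

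Truncated beta-catenin lacks the N-terminal part through which the protein is normally marked for breakdown, and libraries with and without it were compared within T3 medium and within +GF. The targeted gene, Ctnnb1 (chromosome 9, 120929216 to 120960507), was lower with the virus in T3 medium, from 352 ± 6.2 to 279 ± 4.3 CPM (log2 -0.34 ± 0.028), and the table does not separate reads of the construct from those of the normal gene. Targets of Wnt and beta-catenin were higher: in the list 19 of 21 rose and 0 fell (median 2.75, FDR = 2.1e-16). Axin2, a feedback inhibitor and general Wnt target (chromosome 11, 108920349 to 108950783), rose from 0.598 ± 0.15 to 38.9 ± 0.43 CPM (log2 4.65 ± 0.11), and Slc1a2, a pericentral glutamate transporter gene, rose from 0.217 ± 0.040 to 236 ± 2.2 CPM (log2 7.61 ± 0.11). Cyp1a2, Cyp2e1 and Glul rose (log2 7.09 ± 0.083, 5.67 ± 0.21 and 3.40 ± 0.044). The stem cell marker Lgr5 stood at 5.84 ± 0.73 CPM against 0.0122 ± 0.021 CPM. Of pericentral genes 23 of 26 rose and 2 fell (median 2.23, FDR = 4.1e-17), and of periportal genes 2 of 28 rose and 24 fell, 3 and 24 adjusted over the list alone (median -1.63, FDR = 4.1e-17). Otc, Hal and Gls2 gave -4.57 ± 0.049, -4.51 ± 0.066 and -4.36 ± 0.067 but Pigr at 3.61 ± 0.037. In urea cycle and amino acid catabolism 6 of 36 rose and 29 fell (median -0.98, FDR = 5.7e-15), and among plasma proteins 6 of 37 rose and 28 fell, 6 and 30 adjusted over the list alone (median -0.96, FDR = 5.7e-15). Apoa1 gave -2.14 ± 0.024 and Apoc3 at 3.62 ± 0.054.

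Proliferation (35 of 42 rose and 1 fell, median 0.70, FDR = 2.0e-07) and glycolysis (15 of 17 rose and 1 fell, median 1.03, FDR = 5.5e-12) rose with truncated beta-catenin in T3 medium, with Top2a and Pkm at 1.43 ± 0.12 and 3.15 ± 0.055. Cholesterol synthesis fell (2 of 25 rose and 21 fell, median -0.59, FDR = 9.8e-09). Serpine1 and Ndufa4l2 rose (log2 7.40 ± 0.092 and 5.93 ± 0.088), and H19 fell (log2 -6.51 ± 0.14). Y-linked Ddx3y fell by 6.64 ± 0.058 on the log2 scale. Mitochondrially encoded genes fell (12 of 12 fell, median -0.86, FDR = 1.7e-07, adjusted p = 0.11 with an estimated correlation), with mt-Atp6, mt-Co3 and mt-Co2, whose reads may be shared with nuclear copies, at -6.50 ± 0.087, -4.46 ± 0.049 and -3.90 ± 0.045, and mt-Atp8, with none annotated, at -3.40 ± 0.12. Fibroblast markers fell as well (3 of 17 rose and 14 fell, median -0.91, FDR = 0.0047, adjusted p = 0.11 with an estimated correlation). Over all genes limma called 8424 (4125 higher, 4299 lower), 1056 by at least 2-fold; adjusted p-values of the named genes reached 4.2e-14 (limma). No group has an empty virus, and Xist and Y-linked genes differ, so virus, construct and culture are not separated.

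In growth medium the same virus went with higher Wnt target, cell cycle and interferon genes. Ctnnb1 fell from 373 ± 2.1 to 244 ± 3.9 CPM (log2 -0.61 ± 0.028). The Wnt target list had 18 of 21 rose and 1 fell (median 1.5, FDR = 8.2e-09). Cyp1a2, Slc1a2, Glul, Axin2 and Lgr5 gave 4.72 ± 0.083, 3.93 ± 0.11, 3.29 ± 0.044, 2.64 ± 0.11 and 1.37 ± 0.084. For pericentral genes 20 of 26 rose and 4 fell (median 1.33, FDR = 1.5e-07). In proliferation 39 of 42 rose and 1 fell (median 2.33, FDR = 1.3e-18), with Rrm2 and Hmmr at 3.90 ± 0.085 and 3.41 ± 0.13, and Mki67 rose from 5.20 ± 0.52 to 72.5 ± 1.8 CPM (log2 3.57 ± 0.11). Duox2, Nos2, Serpine1, Cxcl5 and Cd68 rose (log2 7.27 ± 0.093, 7.27 ± 0.088, 6.87 ± 0.092, 5.75 ± 0.12 and 5.62 ± 0.11), and Mug2, mt-Atp6, Msln and C8a fell (log2 -9.06 ± 0.057, -5.84 ± 0.087, -5.40 ± 0.089 and -4.88 ± 0.086). Interferon genes (21 of 23 rose and 2 fell, median 0.61, FDR = 5.1e-05), glycolysis (14 of 17 rose and 0 fell, median 1.14, FDR = 1.4e-08) and fibroblast markers (10 of 17 rose and 2 fell, 11 and 2 adjusted over the list alone, median 0.42, FDR = 0.027, adjusted p = 0.17 with an estimated correlation) rose. Col1a1 gave 4.68 ± 0.20 and Col1a2 at 4.45 ± 0.22. Cholesterol synthesis (1 of 25 rose and 22 fell, median -1.07, FDR = 8.9e-12), YAP and cytoskeletal genes (4 of 29 rose and 22 fell, median -0.69, FDR = 5.7e-08) and plasma proteins (7 of 37 rose and 29 fell, median -0.98, FDR = 3.9e-12) fell. Vim and S100a6 gave -4.60 ± 0.072 and -4.43 ± 0.10. Limma called 8993 genes (4371 higher, 4622 lower), 1597 by at least 2-fold, and named genes said to differ had an adjusted p of at most 1.1e-18 (limma).

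The change with the virus differed between the media. In T3 medium it was more positive for Axin2, Cyp1a2, Vim and Areg, by 2.01 ± 0.16, 2.37 ± 0.12, 4.91 ± 0.10 and 4.85 ± 0.17, and more negative for Ddx3y, Plet1 and Mki67, by -6.86 ± 0.082, -4.87 ± 0.10 and -2.24 ± 0.16. The median difference was 1.33 for Wnt targets (FDR = 8.0e-06), 1.30 for pericentral genes (FDR = 1.0e-05), -1.63 for proliferation (FDR = 9.7e-12) and -1.13 for periportal genes (FDR = 1.6e-08). Here limma called 8259 genes (4074 more positive and 4185 more negative), with adjusted p of at most 9.0e-15 for those named. Culture is not separated from medium, as Y-linked genes fell only with T3.

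**Figure D3:**
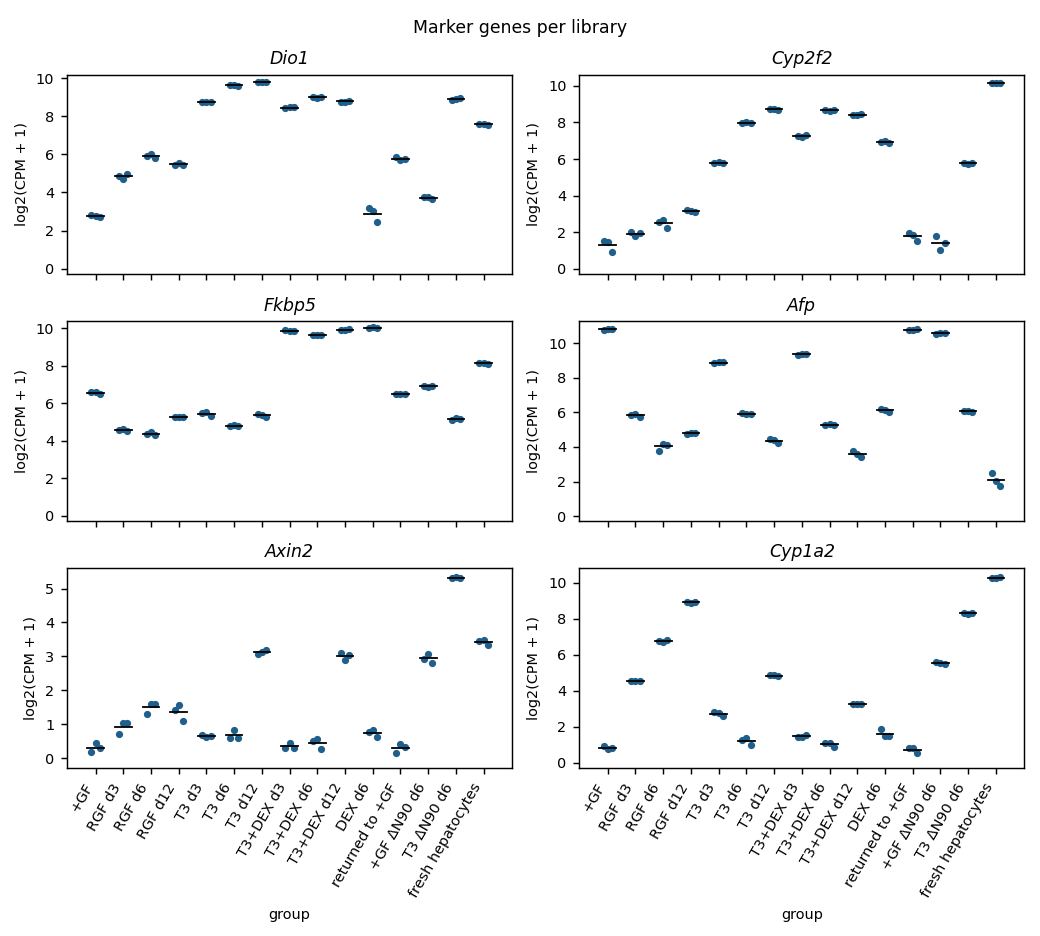
Level of 6 marker genes in each library, as log2(CPM + 1) on the vertical axis, by group on the horizontal axis; points are libraries and the bar is their mean (n = 3). Dio1 stands at 786 ± 11.9 CPM with T3 on day 6 against 5.80 ± 0.30 in +GF, Fkbp5 is highest in the 4 groups with dexamethasone, and Axin2 in T3 medium with truncated beta-catenin (38.9 ± 0.43 CPM).

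Organoids after 12 days with T3 were set against freshly isolated hepatocytes. Most metabolic lists were still lower than in hepatocytes, and fetal, acute phase and bile duct lists higher. Cyp2e1 stood at 3.96 ± 0.83 CPM against 7483 ± 41.5 (log2 -10.57 ± 0.21). Alb stood at 9361 ± 87.2 CPM against 82655 ± 867 (log2 -3.14 ± 0.023). Car3, Igf1 and Ces3a, the last of a gene family with shared sequence and so uncertain, gave -10.20 ± 0.15, -9.12 ± 0.11 and -9.94 ± 0.14. Dio1 stood at 901 ± 5.6 CPM against 190.3 ± 4.8 (log2 2.24 ± 0.086), and Lcn2 stood at 3950.2 ± 45.6 CPM against 18.3 ± 4.7 (log2 7.71 ± 0.073). Scd2 gave 7.0 ± 0.073. For urea cycle and amino acid genes 0 of 36 were higher and 35 lower (median -1.56, FDR = 1.1e-18), for bile acid genes 5 of 25 were higher and 20 lower (median -0.94, FDR = 5.2e-07), and for P450 genes 13 of 58 were higher and 43 lower (median -1.34, FDR = 6.3e-10). Of pericentral genes 3 of 26 were higher and 22 lower (median -2.00, FDR = 2.2e-08), of periportal genes 3 of 28 were higher and 24 lower (median -1.63, FDR = 2.3e-10), and of fatty acid oxidation genes 2 of 32 were higher and 29 lower (median -2.02, FDR = 1.4e-17). Fetal genes (12 of 14 were higher and 1 lower, median 2.20, FDR = 6.2e-06), acute phase genes (15 of 24 were higher and 7 lower, median 1.65, FDR = 4.7e-04), bile duct markers (17 of 21 were higher and 1 lower, median 1.33, FDR = 3.9e-05) and YAP and cytoskeletal genes (20 of 29 were higher and 4 lower, median 1.19, FDR = 6.2e-06) were higher as groups. Endothelial markers were lower than in the hepatocyte preparation (3 of 17 were higher and 12 lower, median -1.30, FDR = 0.0017), with Stab2, a marker of liver sinusoidal cells, at -3.04 ± 0.15. Thyroid targets did not pass as a list: 8 of 20 were higher and 9 lower (median 0.024, FDR = 0.57). In total 9933 genes passed in limma (5253 higher, 4680 lower), 2947 by at least 2-fold, and the highest adjusted p of a named gene that passed was 8.9e-23 (limma).

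With dexamethasone as well, organoids on day 12 held more glycolytic and less pericentral, bile acid and P450 mRNA than hepatocytes. In glycolysis 15 of 17 were higher and 1 lower, 16 and 1 adjusted over the list alone (median 1.37, FDR = 1.4e-08). Pfkp and Pkm gave 7.27 ± 0.051 and 6.75 ± 0.055. Of pericentral genes 2 of 26 were higher and 22 lower (median -2.63, FDR = 5.9e-10), of bile acid genes 2 of 25 were higher and 21 lower (median -1.58, FDR = 5.9e-10), and of P450 genes 9 of 58 were higher and 47 lower (median -1.75, FDR = 2.4e-13). Urea cycle and amino acid genes (4 of 36 were higher and 31 lower, median -1.32, FDR = 3.9e-11) and interferon genes (3 of 23 were higher and 19 lower, median -1.39, FDR = 9.7e-05) were lower. Sult1e1 stood at 1253 ± 4.4 CPM against 1.66 ± 0.66 (log2 8.91 ± 0.18), and Serpine1 stood at 531 ± 11.2 CPM against 1.32 ± 0.29 (log2 7.85 ± 0.092). Car3 and Akr1c6 gave -10.34 ± 0.15 and -9.98 ± 0.13, and Fkbp5 1.78 ± 0.041. Neither gluconeogenesis and glycogen, where 8 of 17 were higher and 9 lower (median -0.72, FDR = 0.52), nor the glucocorticoid list, where 15 of 31 were higher and 14 lower (median 0.11, FDR = 0.51), passed as a list. The genes called by limma numbered 10184 (5323 higher, 4861 lower), 3184 by at least 2-fold, with adjusted p of 4.9e-35 or less (limma) for the named genes.

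**Figure D4:**
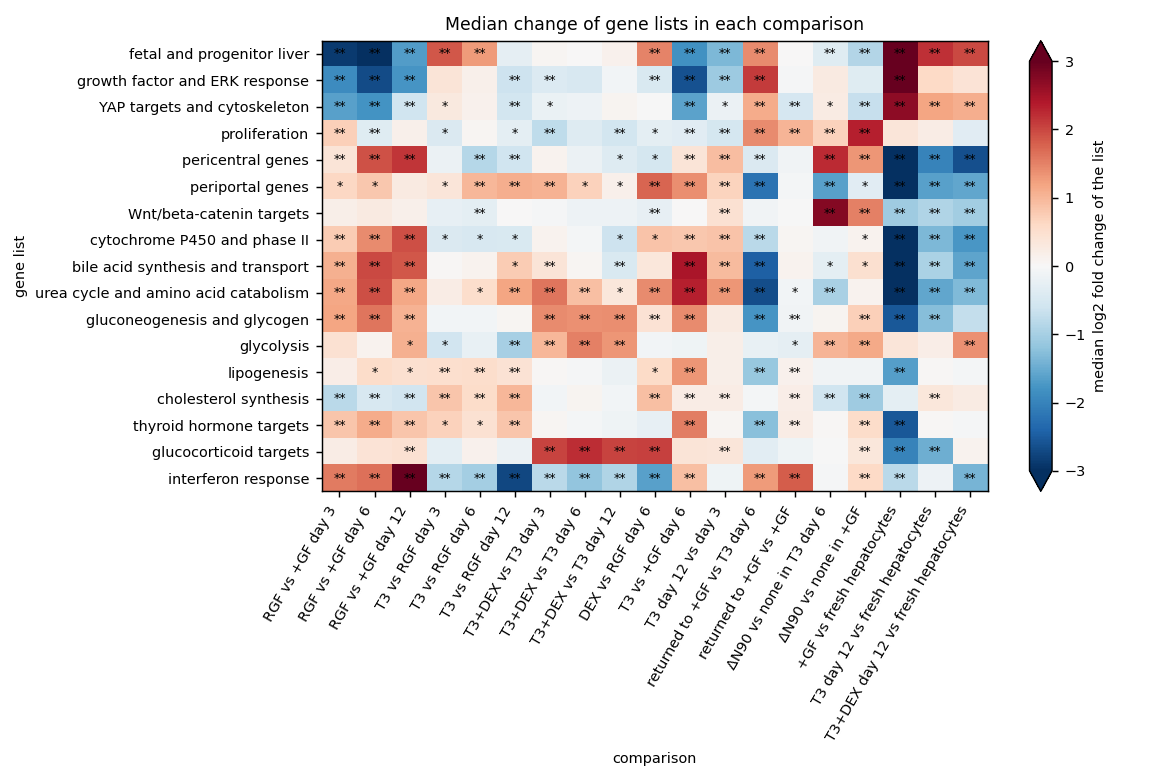
Median log2 fold change (colour) of 17 gene lists (vertical axis) in the 19 pairwise comparisons (horizontal axis), first group over second; one star marks a camera adjusted p under 0.05 and a pair of stars a call also kept with an estimated correlation. The interferon list reaches 3.16 in RGF on day 12 over +GF.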

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

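Chosen only after the result was seen were the tests of a virus effect on Y-linked genes and Xist, of shared copies, of less mitochondrial RNA, of an unlabelled culture difference and of fibroblast RNA. Effects as measured differed between days, hormone backgrounds and media by the interaction test (limma). For T3 on day 12 against day 3, 8823 genes differed, with log2 differences of Saa2 6.26, Thrsp 2.31, H19 -7.38, Cxcl10 -5.76, Hamp -5.23, Ifit3 -5.16 and Alb -2.34, and Pck1 3.36 for a call lost with edgeR and DESeq2 (0.68 and 0.58), and list medians of interferon -2.17, fetal liver -1.63, urea cycle 1.30 and periportal 0.90. For T3 with against without dexamethasone, 8303 genes differed, with Serpine1 11.40, Ndufa4l2 7.42, Cxcl5 6.47, Dio1 2.42, H19 -8.46, Pck1 -2.97 and Cyp2f2 -3.78, and list medians of glycolysis 1.11, fatty acid oxidation 0.82, periportal -1.20 and cholesterol synthesis -0.65. For truncated beta-catenin in T3 medium against +GF, 8259 genes differed, with Axin2 2.01, Cyp1a2 2.37, Vim 4.91, Areg 4.85, Ddx3y -6.86, Plet1 -4.87 and Mki67 -2.24, and list medians of Wnt targets 1.33, pericentral 1.30, proliferation -1.63 and periportal -1.13.

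In each pairwise comparison 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. With A/B for A against B, d for day and virus for truncated beta-catenin against none, real and highest other counts were RGF/+GF d3 10661 and 3, RGF/+GF d6 10647 and 254, RGF/+GF d12 10022 and 1, T3/RGF d3 9895 and 1, T3/RGF d6 9828 and 136, T3/RGF d12 9592 and 0, T3+DEX/T3 d3 7226 and 2, T3+DEX/T3 d6 8962 and 0, T3+DEX/T3 d12 7244 and 2 and DEX/RGF d6 9722 and 183. Those for the other comparisons were T3/+GF d6 9293 and 0, T3 d12/d3 7986 and 0, returned/T3 d6 9308 and 0, returned/+GF 5783 and 7, virus in T3 8424 and 0, virus in +GF 8993 and 911, +GF/hepatocytes 11074 and 0, T3 d12/hepatocytes 9933 and 1 and T3+DEX d12/hepatocytes 10184 and 24. For each interaction 1 of 100 drawn splits, the real one, gave as many genes: T3 by DEX 8303 against 8095, T3 by day 8823 against 8030 and virus by medium 8259 against 6997. Splits that keep the grouping of one arm show that arm's own effect, and replicates may be technical. The counts thus decide neither chance nor the interaction.

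Tdtomato (986 CPM) and Cre (5.91 CPM), signals outside the measurement of interest, were highest in RGF on day 3. Xist was highest in T3 medium with the virus, where Y-linked genes were low. An effect of the virus on Y-linked genes that holds in both media is argued against, as these had a median log2 fold change of 0.0623 with the virus in +GF. For Xist the virus cannot be told apart from culture, as they are confounded. Its mean in +GF was 3.72 CPM, unevenly between replicates, and no library without the virus exceeded 0.372 CPM. Organoids of another sex may lie behind the T3 libraries with the virus. Values of -6.64 to -4.58 for 4 Y-linked genes argue against the same sex with and without it. There 4 genes that escape X inactivation had a median of 0.371, though Ddx3x gave -0.19. Where the reporter in RGF on day 3 comes from was not tested.

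With truncated beta-catenin the neighbouring mitochondrial genes mt-Co2, mt-Atp8, mt-Atp6 and mt-Co3 fell in both media, by log2 fold changes of -3.90, -3.40, -6.50 and -4.46 with T3 and -3.43, -2.68, -5.84 and -3.86 in +GF. Less mitochondrial RNA as a whole is argued against as the whole cause: the 5 other genes with little or no annotated nuclear copy had a median of 0.287 in +GF and -0.520 in T3 medium. There they fell by 0.30 to 0.97, so a smaller fall of all may add to it in T3 medium. Reads shared with nuclear copies cannot be told from a virus effect: over 12 mitochondrial genes the share in a copy and the change had a Spearman rho of -0.513 (permutation test, p = 0.091), too few to decide. The fallen mt-Atp8 has no annotated copy, but its neighbours do, and mt-Nd3, 98.0% in one, gave -1.20 with T3 and 0.027 in +GF. A strain difference in mitochondrial sequence and an effect of beta-catenin itself stay open, as untested.

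Nos2, Duox2 and Cxcl5 were high in RGF without hormones and with truncated beta-catenin, with mean Nos2 of 79.3 CPM or more in these 5 groups and 0.934 CPM or less in the other 10; Col1a1 was higher in RGF and in +GF with the virus. RNA from fibroblasts as the source is argued against with the virus in T3 medium, where the fibroblast list had a median of -0.912; the other groups stay open. An unlabelled difference between cultures shared by these groups may contribute: across genes, which are not replicates, the change with the virus in +GF followed that of RGF over T3 medium on day 6 with a Spearman rho of 0.338, from separate libraries. Effects of the hormones and of beta-catenin on these genes, which the design names, stay open as well.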

How the results depend on the processing

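The fits without sex-linked and mitochondrial genes, the fits without the RGF day 3 and virus libraries, and the 2-fold counts were chosen only after the data were seen. All 430 counts of called genes under the alternatives lay within 1.5 times the main count. Of 7228 alternative values of named genes, 7224 kept direction and call, and 0 reversed. The 4 lost calls were Alb for +GF/hepatocytes and T3+DEX/T3 d3, and Pck1 for T3 by day. Quantile normalization gave Alb, top gene there, 0 by construction (main log2 0.23 and 0.73). Pck1 gave 0.68 with edgeR and 0.58 with DESeq2 (main 3.36, cause untested). Without sex-linked and mitochondrial genes the counts with the virus were 8145 in T3 medium and 8723 in +GF, and the fit without the doubted libraries gave 5937 genes for returned/+GF and 11134 for +GF/hepatocytes. Leaving out each library gave 5013 to 5583 genes for returned/+GF and 10787 to 10832 for +GF/hepatocytes, the comparisons with the fewest and most calls. No scaling moved the share of higher calls by more than 8.21 points (quantile normalization, returned/+GF). With an estimated correlation 103 of 400 called lists lost the call. Genes under about 1 CPM were not tested, and folds of low genes rest on few reads.

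Counts of genes changed by at least 2-fold moved by over 1.5 times in these cases (main to alternative). A larger pseudocount shrinks the folds of low genes by construction, and the cause was not tested for edgeR and DESeq2. With a pseudocount of 0.1, T3/RGF d6 1753 to 2755, T3/RGF d12 1898 to 2850, T3+DEX/T3 d3 960 to 1713, T3+DEX/T3 d6 1300 to 2135, T3+DEX/T3 d12 1018 to 1789, DEX/RGF d6 1897 to 2909, T3 d12/d3 961 to 1782, returned/+GF 407 to 815, virus in T3 1056 to 1891, virus in +GF 1597 to 2402 and T3 by DEX 1649 to 2511. With a pseudocount of 5, RGF/+GF d3 3234 to 1950, RGF/+GF d6 3444 to 2125, RGF/+GF d12 2482 to 1498, T3/RGF d3 2060 to 1138, T3/RGF d6 1753 to 943, T3/RGF d12 1898 to 1085, T3+DEX/T3 d3 960 to 535, T3+DEX/T3 d6 1300 to 729, T3+DEX/T3 d12 1018 to 581, DEX/RGF d6 1897 to 1114, T3/+GF d6 2013 to 1199, T3 d12/d3 961 to 515, returned/T3 d6 1975 to 1161, returned/+GF 407 to 159, virus in T3 1056 to 539, virus in +GF 1597 to 823, T3 d12/hepatocytes 2947 to 1759, T3+DEX d12/hepatocytes 3184 to 1911, T3 by DEX 1649 to 896, T3 by day 2260 to 1308 and virus by medium 1667 to 827. With edgeR on recovered reads, T3/RGF d3 2060 to 3152, T3/RGF d6 1753 to 2894, T3/RGF d12 1898 to 3020, T3+DEX/T3 d3 960 to 1767, T3+DEX/T3 d6 1300 to 2299, T3+DEX/T3 d12 1018 to 1951, DEX/RGF d6 1897 to 3050, T3 d12/d3 961 to 1940, returned/T3 d6 1975 to 3018, returned/+GF 407 to 880, virus in T3 1056 to 1981 and virus in +GF 1597 to 2510. With DESeq2 on recovered reads, T3/RGF d3 2060 to 3176, T3/RGF d6 1753 to 2917, T3/RGF d12 1898 to 3051, T3+DEX/T3 d3 960 to 1803, T3+DEX/T3 d6 1300 to 2308, T3+DEX/T3 d12 1018 to 1971, DEX/RGF d6 1897 to 3058, T3 d12/d3 961 to 1954, returned/T3 d6 1975 to 3024, returned/+GF 407 to 881, virus in T3 1056 to 2002, virus in +GF 1597 to 2527 and T3 by DEX 1649 to 2476.

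Values of similarity to hepatocytes moved by more than the spread between replicates; the cause was not tested beyond the other genes and measure used. The order of groups is +GF, RGF, T3 and T3+DEX on days 3, 6 and 12, DEX, returned, and virus in +GF and in T3. The correlation was 0.700, 0.795, 0.835, 0.792, 0.807, 0.849, 0.861, 0.835, 0.848, 0.842, 0.877, 0.691, 0.702 and 0.810 with genes over 5 CPM, and 0.770, 0.840, 0.838, 0.850, 0.882, 0.891, 0.869, 0.882, 0.876, 0.901, 0.763, 0.767 and 0.853 as Pearson's, without RGF d6, which moved by less. The share was 37.8, 33.9, 29.4, 22.8, 40.8, 34.1, 25.6, 46.0, 36.0, 30.6, 40.5, 37.1, 34.0 and 26.1% for 50 genes and 55.0, 56.3, 54.0, 46.4, 60.6, 56.9, 50.0, 64.9, 58.3, 52.1, 62.3, 54.2, 52.2 and 50.2% for 500 genes. With the genes chosen leaving out each hepatocyte library it was 43.0 to 43.6, 40.1 to 41.3, 36.3 to 37.0, 28.7 to 29.0, 46.8 to 47.9, 41.1 to 42.0, 32.2 to 32.9, 51.7 to 52.7, 43.1 to 43.6, 36.6 to 37.2, 47.1 to 47.8, 42.2 to 42.9, 38.9 to 39.6 and 33.5 to 34.0%.

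Groups share replicate numbers, but whether these pair the samples stays open. Correlations of same-numbered libraries ran from -0.12 to 0.28, and in 0 of 19 comparisons did every pair exceed 0.1. With a replicate block, 5832 genes were called for returned/+GF (5783 without) and 11086 for +GF/hepatocytes (11074 without), 1 of 400 lists lost its call (mitochondrially encoded, virus in +GF), and 26 of 45 libraries correlated best with one of their own number, which is a hint from the data only.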

Other observations

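Both correlation tests in this part were planned before their results were seen. Gene groups not yet described also moved. Integrated and ER stress genes fell from day 3 to day 12 with T3, where 4 of 23 rose and 18 fell (median -0.55, FDR = 2.2e-06). Chac1 and Phgdh gave -1.96 ± 0.14 and -1.87 ± 0.12. Immediate early genes were lower with T3 than in RGF on day 12 (2 of 20 rose and 14 fell, median -0.89, FDR = 1.1e-04). Btg2 and Junb gave -2.41 ± 0.047 and -2.33 ± 0.061. Markers of intestinal and other non-hepatic epithelium were lower as well (3 of 11 rose and 8 fell, median -1.15, FDR = 0.012). Tff3 and Sprr1a gave 4.70 ± 0.11 and -4.47 ± 0.11. Mitochondrially encoded genes were higher with T3 on day 12 (12 of 12 rose, median 1.63, FDR = 2.1e-07, adjusted p = 0.083 with an estimated correlation), with mt-Cytb and mt-Atp6 at 3.19 ± 0.040 and 3.02 ± 0.087. With truncated beta-catenin in +GF, 3 of 5 rose and 0 fell (median 1.81, FDR = 0.014) among lymphocyte and neutrophil markers, with the antigen presentation genes H2-Ab1 and Cd74 at 3.73 ± 0.12 and 3.18 ± 0.11.

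One hypothesis was that T3 changes largely the same genes on day 3 and day 12. Spearman rho across genes, from comparisons that share no library, was 0.425, between the bounds set for and against it, so it stays undecided. Another was that dexamethasone acts largely alike with and without T3, and rho was 0.471, undecided likewise.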
